A study of Mus musculus with 391 samples.

How the data were processed

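The data are single cells from dissociated vascular fragments of adult mouse brain, sorted into wells of plates and sequenced with Smart-seq2, a full-length protocol without molecular identifiers, per the labels. The deposited values are whole-number counts of reads per gene, not normalized, for 56941 genes and 391 cells. Per the submitters' processing notes, SAMtools 1.16.1, featureCounts and Subread 1.4.6-p5 were used with genome build GRCm39. The aligner, the gene annotation, the treatment of duplicate and multiply mapped reads and the use of strand are not given in the sources used here. Genes that share reads with near-identical copies, such as glycolytic enzymes and ribosomal proteins with pseudogenes, are therefore uncertain, and so are overlapping and antisense genes. The reference annotation at hand (GENCODE M21) is of an older build, so no coordinates are printed, and genes carry the symbols of the table.

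Each cell's class was taken from the labels, with 280 microglia and 111 endothelial cells. Columns of the count table were matched to a class through a deposited cell table, whose 2 codes occur 280 and 111 times. No sample label ties a cell to an animal, so each class is 1 sample and no test, p-value or standard error was computed from cells. The plate was read from the start of each column name; plates A and B hold both classes, C and D only endothelial cells. No count column was left out, 0 columns were identical, and 31131 genes had 0 reads in all cells. No filter on cells was applied. Each well was deposited as 1 cell and no doublet caller was run; the level of the opposite class's markers was measured instead.

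Reads were summed over the cells of a class and divided by all gene reads of the class to give CPM. Sums have exact Poisson intervals and ratios exact conditional binomial intervals, at 95%. A class with 0 reads was set to a floor of 3 reads over the class, and the ratio is then a bound. The log2 ratios use a pseudocount of 1 CPM, which understates the ratio of low genes. Members of a gene list count as measured at 1 CPM or more in either class, and as higher in a class at 4-fold or more on that scale. A list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these cells. With members of 0 reads set at their floor and no pseudocount, the median was 9.68 for the microglia core, 9.88 for border-associated macrophages, -6.94 for the endothelial core, 7.03 for chemokines and -11.37 for fenestrated endothelium. It was also 5.12 for cell cycle (2.37 with the pseudocount), -6.83 for arterial (-3.95), -4.60 for mural (-2.70) and 3.44 for neuron genes (1.50). For shares of cells with a read, cells were also thinned to 71000 reads.

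Before the data were examined, 38 gene lists and the rule for named genes were fixed. The lists cover the microglia and endothelial cores, barrier transporters, junctions, arterial, capillary and venous endothelium, tip cells, Wnt targets with barrier transcription factors, homeostatic and disease-associated microglia, border-associated macrophages, immediate early genes, chemokines, interferon-stimulated genes, antigen presentation, complement, pattern recognition and Fc receptors, purinergic genes, ion channels, lysosome, glycolysis, oxidative phosphorylation, cell cycle, ligands, receptors, adhesion, coagulation, sex chromosomes and 9 further cell types. A fenestrated endothelium list and a dendritic cell list were added later. The rule named the 12 largest ratios per direction among genes at 50 CPM or more and read in at least 50% of the higher class, leaving out mitochondrial, ribosomal protein and predicted genes. It also named the up to 4 most abundant members of each list with its most extreme member, the sex chromosome genes and the 5 most abundant genes per class. Some genes that the rule names are not reported here.

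Clusters were made within each class from log CPM values of 2000 variable genes, 20 principal components, 15 neighbours and the Leiden method at resolution 0.5. Markers fixed in advance named a cluster where their list stood higher in it than in the other cells of the class and at least 3 markers were read in at least 50% of its cells. How much higher was not fixed, and which clusters to name was judged after the levels were seen. The steps were tested on simulated data drawn from the real means and depths of 56941 genes with 200 genes changed, for the comparison of microglia with endothelial cells. The 95% interval held the true ratio for 94% of changed genes, 100% of genes changed 8-fold were sized at 4-fold or more, 0% of those changed 2-fold were, and 0 of 13557 unchanged genes were. The simulated reads were Poisson counts from 1 mean per gene and class, without further variation between cells. They do not show how the intervals and sizes perform where cells of a class differ, as they do here. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, with R 4.3.3 and edgeR 4.0.16 for the TMM factors of an alternative scaling. The alternatives were the mean of per-cell CPM, TMM, totals without mitochondrial and ribosomal protein genes, leaving out shallow cells, cells with markers of the opposite class or the highest cell of each gene, other pseudocounts (0.1 and 10) and filters, thinning, a minimum of 10 reads for a share, and other cluster settings. Plates A and B alone and cluster 3 alone were added after seeing the data.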

Results

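Single cells from dissociated vascular fragments of adult mouse brain were profiled by full-length RNA sequencing in sorted plates. The labels put 280 cells in a microglia class and 111 in an endothelial class. Microglia are the resident macrophages of the brain, and endothelial cells line its blood vessels. The deposited table held 68869241 reads assigned to genes, 47508014 in microglia-class cells and 21361227 in endothelial cells. A microglia-class cell had a median of 146506 gene reads (range 39876 to 504875), and an endothelial cell 174345 (range 83954 to 602175). Median genes with a read per cell were 2690 and 2684, and 2177 and 2086 after each cell was thinned to 71000 reads, which left out 34 microglia-class cells and 0 endothelial cells. No animal is named, so each class counts as 1 sample. Values are CPM, the reads of a gene scaled to the gene reads of its class, pooled over the cells, with no test between classes. Parentheses after CPM values and ratios hold exact 95% intervals, and those after shares of cells hold 95% Clopper-Pearson intervals. These reads carry no molecular identifiers, so intervals and floors cover counting error only. The intervals of shares treat cells as independent draws and do not measure variation between animals.

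The cells came from 4 plates, told apart by the column names of the table and called A to D here. Plates A and B held cells of both classes, 133 and 147 microglia-class cells with 7 and 10 endothelial cells. The other 50 and 44 endothelial cells came from plates C and D, which held no microglia-class cell. On the plates shared by the classes, microglia-class cells sat in rows I to P and endothelial cells in rows A to H. Median gene reads were 122714 and 199821 for microglia-class cells on plates A and B, against 135028 and 185736 for endothelial cells. Values within these plates stand beside the pooled ones, and they rest on 7 and 10 endothelial cells. Over all genes at 1 CPM or more, the median log2 ratio was 0.36 pooled (14989 genes). It was 1.73 within plate A (14160) and 1.87 within plate B (13649). Lists did not all share this shift. The oxidative phosphorylation list's median was -0.15 pooled, -0.32 within plate A and -0.34 within plate B. A list's value within a plate is therefore best read against random lists matched on expression.

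The comparison of the classes asked which transcripts separate brain microglia from brain endothelium. Plvap, the diaphragm protein of fenestrae, stood at 7837 (7799.6 to 7875) CPM in endothelial cells and was read in 100% (96.7 to 100) of them. Igfbp3, a binding protein of insulin-like growth factors, reached 5145 (5115 to 5176) CPM, and Plpp3 and Plpp1, lipid phosphatases, 3616 and 2553 CPM. Esm1, a secreted proteoglycan of growing endothelium, stood at 1434 CPM and Cd24a, a surface glycoprotein, at 2119 CPM. In the microglia class Plvap was at 1.52 CPM, a ratio of 5171-fold (4106 to 6609). Each of the 8 members of a fenestrated endothelium list was at least 4-fold higher in endothelial cells. The list's median log2 ratio of microglia class over endothelial class was -9.73, below all 10000 random lists matched on expression, and -9.93 within plate A and -9.66 within plate B. The endothelial core, junction and arterial lists also lay below all random lists. A ratio to the microglia class therefore does not tell fenestrated from barrier endothelium. The fenestrated endothelium list was written after the class codes of the deposited cell table had been read and before any gene value was seen. In endothelial cells the list's members ran from 440.1 CPM for Exoc3l2 to 7837 for Plvap, and those of the blood-brain barrier transporter list from 0.234 for Lrp8 to 916 for Slc3a2, so the lists overlapped. Some barrier genes were low in these cells: Cldn5, the main claudin of the barrier, 263 CPM, Slc2a1, its glucose transporter, 182, Abcb1a, a drug efflux pump, 40.2, Slco1c1, a thyroid hormone transporter, 5.15, and Mfsd2a, a lipid transporter, 2.53. Abcb1a, Slco1c1, Cldn5, Mfsd2a, Exoc3l2 and Lrp8 lie outside the rule for named genes and were chosen after their values were seen. Plvap lay between 6418 and 8072 CPM on all 4 plates, and Slc2a1 between 37.4 and 491.

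**Figure D1:**
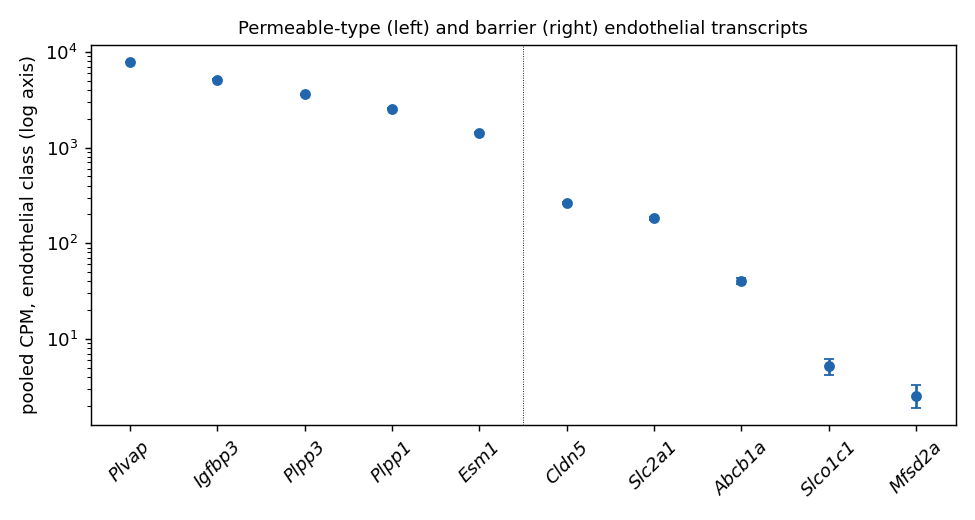
Pooled CPM in the 111 endothelial cells on a log axis, with exact 95% Poisson bars, for 5 transcripts of fenestrated or growing endothelium on the left and 5 of the blood-brain barrier, mostly chosen after their values were seen, on the right. Plvap stood at 7837 CPM and Mfsd2a at 2.53, while the barrier list's Slc3a2, not shown, stood at 916.

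Of 23 blood-brain barrier transporters, 6 were at least 4-fold higher in endothelial cells, 2 were at least 4-fold higher in the microglia class and 15 lay between. Some of those between were low genes, whose ratios the pseudocount understates. Over the plates, Mfsd2a stood at 1.02 to 6.60 CPM in endothelial cells, Slc7a5 at 1.14 to 4.16 and Slco1c1 at 1.94 to 20.8. These genes were picked after their values were seen. A place between is thus no sign of shared expression for such genes. The list's median log2 ratio was -0.41, at percentile 6.02 of the random lists. It was -0.99 within plate A and -1.43 within plate B, at percentiles 0.21 and 0.02, so the list stood apart towards endothelial cells within the plates and not pooled. Insr, the insulin receptor, stood at 479 against 36 CPM, and Abcg2, an efflux pump, at 459 against 17.2. Slc3a2, the heavy chain of amino acid exchangers, was at 788 CPM in the microglia class and 916 in endothelial cells, and Slco2b1, an organic anion transporter, at 639.7 and 420.2. Slc6a6, the taurine transporter, was at 476 and 866 CPM.

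The general endothelial markers separated the classes. Of the 20 members of the endothelial core list, 19 were at least 4-fold higher in endothelial cells, the exception being Slc2a1. The median log2 ratio was -6.52 (-7.06 and -6.83 within the plates), below all random lists. Eng, a co-receptor of the TGF-beta family, reached 4819 (4789.7 to 4849) CPM against 115 in the microglia class, Emcn, an endothelial sialomucin, 3226 against 3.3, Flt1, a receptor of VEGF, 3183 against 7.87, and Kdr, the main receptor of VEGF, 2888 against 4.82. Slc2a1 was 2.26-fold (2.16 to 2.37) higher in endothelial cells pooled, but stood at 53.3 against 37.4 CPM within plate A, where it was lower in them. Among 18 measured junction genes, 14 were at least 4-fold higher in endothelial cells, 1 in the microglia class and 3 lay between, with a median of -3.40 (-3.70 and -2.63 within the plates). Pecam1, an adhesion molecule of endothelial contacts, stood at 2597 against 60.1 CPM and Esam, another, at 2189 against 4.95. Ctnnb1, beta-catenin, was at 1218 against 195, and F11r, a junctional adhesion molecule, at 886 against 419. The member higher in the microglia class was Marveld2, at 17.5 against 0.702 CPM and read in 8.21% of that class.

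Vessel segment lists differed among themselves, but a ratio to the microglia class does not tell 1 segment of endothelium from another. Of 13 measured arterial genes, 11 were at least 4-fold higher in endothelial cells (median -3.95, -7.07 within plate A and -4.34 within plate B), among them Dll4, a Notch ligand, at 570.3 against 0.316 CPM and Gja4, a connexin, at 239 against 0.463. Gkn3, Bmx and Cytl1 of the same list reached at most 1.14, 1.41 and 0.228 CPM in endothelial cells on any plate. They were picked after their values were seen. Gja5, another connexin, was at 2.55 CPM in the microglia class and 0.234 in endothelial cells. Few cells carried it: it was read in at most 1.96% of the cells of any microglia-class cluster, and in 8% of endothelial cells on plate C. Of 12 capillary genes, 4 were at least 4-fold higher in endothelial cells and 8 lay between (median -1.43, -2.03 within plate A and -1.43 within plate B). Those between again included the low genes Mfsd2a, Slc7a5 and Slco1c1. Rgcc, a regulator of the cell cycle, stood at 1554 against 1.26 CPM, Tgm2, a transglutaminase, at 1209 against 25.7, and Cxcl12, a chemokine, at 828 against 11.6. The 10 measured venous genes had a median of 0.29 (0.25 and 0.99 within the plates) at percentile 49.7, with Ephb4, a venous receptor, at 374 CPM in endothelial cells against 0.316. Of 12 tip cell genes, 7 were at least 4-fold higher in endothelial cells and 2 in the microglia class (median -4.11, -3.87 within plate A and -1.71 within plate B), with the basement membrane collagens Col4a2 and Col4a1 at 1570.2 and 1383 CPM against 0.674 and 0.905. Cxcr4, the receptor of Cxcl12, was at 20.6 CPM in the microglia class against 1.26. Of 11 measured Wnt targets and barrier transcription factors, 6 were at least 4-fold higher in endothelial cells (median -2.42, -1.54 within plate A and -1.02 within plate B). Sox18 and Sox17, endothelial transcription factors, stood at 1679 and 173 CPM against 2.88 and 1.56, and Foxf2, a transcription factor, at 98.4 against 0.631.

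Macrophage genes were high in the microglia class. All 20 microglia core genes were at least 4-fold higher in it, with a median log2 ratio of 8.97 (8.30 and 8.16 within the plates), above all 10000 random lists. Csf1r, the receptor that macrophages need for survival, stood at 4524 (4505 to 4543) CPM against 17, a ratio of 265-fold (239.6 to 295). C1qa, C1qb and C1qc, the chains of the first complement component, reached 3472, 4253 and 3644 CPM against 4.49, 5.48 and 4.21. Of 16 homeostatic microglia genes, 12 were at least 4-fold higher and 4 lay between (median 7.35, 7.49 within plate A and 7.17 within plate B), with Cx3cr1, the fractalkine receptor, at 2067 against 5.2 CPM and Fcrls, an Fc receptor-like protein, at 2146 against 1.59. Mef2c, a transcription factor, was at 596 and 549. Of 20 disease-associated microglia genes, 17 were at least 4-fold higher in the class and 1, Csf1, in endothelial cells (median 5.26, 6.43 within plate A and 5.89 within plate B, and 2.68 for the 51 microglia-like cells of cluster 3 alone). Apoe, a lipid carrier, reached 6939 CPM against 524, with 11123 in cluster 1 and 1496 in cluster 3, Ctsb and Ctsd, lysosomal proteases, 4861 and 1917 against 695 and 379, and Fth1, ferritin heavy chain, 3315 against 1146.

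Markers of border-associated macrophages, which line the meninges and vessels of the brain, were also high in this class. All 14 were at least 4-fold higher in the microglia class, with a median of 7.04 (7.60 and 7.81 within the plates), above all random lists. Mrc1, the mannose receptor, stood at 1837 (1824 to 1849) CPM against 1.08 and was read in 95.4% (92.2 to 97.5) of cells, F13a1, a coagulation factor chain, at 832 against 0.609, and Stab1 and Dab2, endocytic proteins, at 1552 and 1326 against 335 and 270.4. At 10 or more reads, 36 of 280 cells (12.9%, 9.17 to 17.4) carried Sall1, a transcription factor of microglia, without Mrc1, while 186 (66.4%, 60.6 to 71.9) carried Mrc1 without Sall1. Only 2 cells (0.714%, 0.0866 to 2.56) carried both, and 56 neither. Sall1 and Mrc1 as a pair were chosen after the cell clusters had been seen, and other pairs were less exclusive. At 10 or more reads, P2ry12 and Mrc1 were together in 85 cells (30.4%, 25.0 to 36.1) against 56 with P2ry12 alone, and Tmem119, a microglia marker, and Ms4a7, a border-associated macrophage marker, in 24 (8.57%, 5.57 to 12.5) against 53 with Tmem119 alone.

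Clustering the microglia class alone gave 4 clusters, and the endothelial class gave 1. Cluster 3, with 51 cells (18.2%, 13.9 to 23.2), was microglia-like: Slc2a5, Il1a, Adgrg1 and Sall1 led it, and all 20 core markers were read in at least 50% of its cells, as were 18 in each other cluster. Cluster 1, with 128 cells (45.7%, 39.8 to 51.7), was border-associated-macrophage-like, with 10 of 14 such markers read in at least 50% of its cells, against 9, 7 and 9 in clusters 2 to 4, so the name rests on their level. Its leading genes included F13a1, Cd38 and Ccl24, and also Egfl7, a marker of endothelium. Cluster 2, with 70 cells (25%, 20.0 to 30.5), was led by Lyz1, Axl, Cd72 and Ccr2, with Cd74 and H2-Ab1 of antigen presentation among its leading genes. Cluster 4, with 31 cells (11.1%, 7.65 to 15.3), was led by Napsa, Mcemp1, Il1r2 and Itgb7. The microglia core list's median log2 ratio of a cluster over the other cells of the class was -0.74, 0.06, 1.75 and -4.25 for clusters 1 to 4, and that of border-associated macrophages 2.54, -0.54, -5.98 and -5.56. For cluster 2 the other cells include the 128 of cluster 1. Against cluster 3, cluster 2 was higher for Mrc1 (1752 against 74.4 CPM) and F13a1 (472 against 5.80). Lyve1 and Cd209f were at 1.04 CPM or less in both. Clusters 2 and 4 were left unnamed. Clusters 1 to 4 held 69, 32, 24 and 8 cells of plate A and 59, 38, 27 and 23 of plate B. Their median gene reads were 124239, 140158, 196450 and 218500, and cluster 4 also had the highest median of genes with a read, 3623. Leading genes define the clusters and are no finding about them. With the 51 cells of cluster 3 set against all endothelial cells, the microglia core list kept 20 members at 4-fold, with a median of 9.59, while the border-associated macrophage list had 4 of 14 and a median of 1.50.

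**Figure D2:**
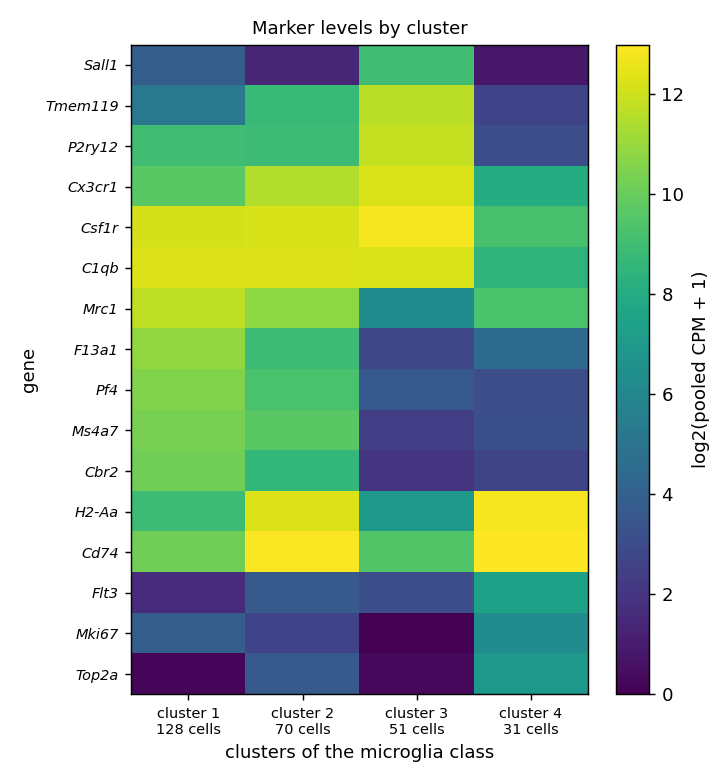
Levels of 16 genes in the 4 clusters of the microglia class, as log2 of pooled CPM plus 1, with genes in rows and clusters in columns. Sall1 stood at 507 CPM in cluster 3 and 13.3 in cluster 1, and Mrc1 at 74.4 and 3386. The clusters were made from the same values.

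Immune effector lists were higher in the microglia class. Of 24 measured chemokines and cytokines, 18 were at least 4-fold higher in it and 4 in endothelial cells (median 4.69, 5.97 within plate A and 6.63 within plate B). Ccl4 and Ccl3, chemokines of macrophages, stood at 898 and 785 CPM against 1.12 and 0.609. Cx3cl1, the ligand of Cx3cr1, was at 1133 in endothelial cells against 13.5. Of 19 complement genes, 13 were at least 4-fold higher in the microglia class and 2 in endothelial cells (median 6.45, 6.03 within plate A and 6.90 within plate B), with C3ar1, the receptor of C3a, at 868 against 0.515 CPM and Cd59a, an inhibitor of lysis, at 19.4 in endothelial cells against 0.779. Of 27 pattern recognition and Fc receptors, 22 were at least 4-fold higher in the microglia class (median 6.17, 6.44 within plate A and 6.26 within plate B). Fcgr2b, Fcgr3 and Fcer1g, subunits of Fc receptors, stood at 1384, 1157 and 1281 CPM against 0.702, 0.421 and 1.87, while Nod1, a sensor of bacterial peptides, was at 259 in endothelial cells against 31.1. Of 24 lysosomal and phagocytic genes, 17 were at least 4-fold higher in the microglia class and 0 in endothelial cells (median 2.38, 3.59 within plate A and 3.48 within plate B), led by Lyz2, lysozyme, at 4059 against 10.9 CPM, and Laptm5, a lysosomal membrane protein, at 3452 against 4.26.

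Antigen presentation genes differed among themselves. Of 20 genes, 9 were at least 4-fold higher in the microglia class and 11 lay between (median 0.50, percentile 93.4). The median was 2.75 within plate A and 1.36 within plate B, at percentiles 100 and 99.9, but -0.16 at percentile 33.6 for cluster 3 alone. Cd74 and H2-Aa, of MHC class II, stood at 3732 and 2541 CPM against 42.9 and 72.7, with H2-Aa at 4939 and 7023 in clusters 2 and 4 and 118 in cluster 3, and Cd86, a costimulatory ligand, at 356 against 0.234. H2-D1 and B2m, of MHC class I, were at 2218 and 2442 in the microglia class and 2653 and 2121 in endothelial cells. The 23 interferon-stimulated genes had a median of -0.03 (0.95 and 0.64 within the plates) at percentile 42, with Ifitm3, an antiviral membrane protein, at 433 and 822 CPM and Bst2, tetherin, at 368 and 379. Mx1, an antiviral GTPase, was at least 348-fold higher in the microglia class, with 0 reads in endothelial cells and a floor of 3 reads over that class. Immediate early genes, which dissociation can induce, had 6 of 24 members at least 4-fold higher in the microglia class and 18 between (median 1.12, above all random lists, and 0.89 within plate A and 1.13 within plate B). Within plates A and B the list's median lay below that of all genes, but at percentile 99.9 and 100 of random lists matched on expression. Fos, Dusp1 and Zfp36 stood at 4343, 2828 and 3292 CPM against 2010.1, 1285 and 872, and Jun was at 3213 and 2575. Egr2 was at 219 against 0.0936 CPM.

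Ligands and receptors that could pair the classes were spread over both. Of 33 measured ligands, 12 were at least 4-fold higher in the microglia class, 13 in endothelial cells and 8 lay between (median -1.29, percentile 0.01). Within plates A and B the median was 0.05 and 0.11, below that of all genes there, at percentiles 18.6 and 13.0. Gas6, a ligand of TAM receptors, stood at 1624 CPM in endothelial cells and 661 in the microglia class. Csf1, a ligand of Csf1r, was at 116 CPM in endothelial cells and 25.1 in the microglia class pooled, but at 0 and 22.3 within plate A. Of 41 measured receptors, 12 were at least 4-fold higher in the microglia class and 21 in endothelial cells (median -2.13, -0.40 within plate A and -1.35 within plate B, at percentile 15.4 on plate A and 0.03 on plate B). Of 18 adhesion genes, 7 were at least 4-fold higher in the microglia class and 5 in endothelial cells (median 0.27, percentile 76.8). The median was 3.79 within plate A and 1.63 within plate B, at percentiles 100 and 99.3, but -1.36 at percentile 0.38 for cluster 3 alone. Selplg, a ligand of selectins, stood at 1314 against 0.655 CPM, Sirpa, the receptor of Cd47, at 1306 against 1.03, and Cd34, a sialomucin, at 1576 in endothelial cells against 125. Of 19 coagulation genes, 5 were at least 4-fold higher in endothelial cells and 3 in the microglia class (median -1.02, percentile 0.22, -0.22 within plate A and -1.07 within plate B, at percentile 24.8 on plate A), with Thbd, thrombomodulin, at 1449 against 55.3 CPM. Of 16 purinergic genes, 9 were at least 4-fold higher in the microglia class and 4 in endothelial cells (median 2.66, 3.06 within plate A and 2.86 within plate B). P2ry12, P2ry13 and P2ry6, nucleotide receptors, stood at 1093, 778 and 799 CPM against 0.843, 0.515 and 25.3, while Alpl, a phosphatase, was at 675 in endothelial cells against 2.02. Of 18 ion channel genes, 6 were at least 4-fold higher in the microglia class and 5 in endothelial cells (median 0.41, 4.22 within plate A and 2.78 within plate B), with Clic4 at 916 against 167 CPM and Trpv2 at 159 against 0.14. The ion channel list stood at percentile 65.8 pooled, 77.3 on plate A and 73.9 on plate B, so it did not stand apart from random lists.

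Metabolic lists differed less. The 18 glycolysis genes had a median of -0.58 (0.38 and -0.13 within the plates) at percentile 4.55 (64.0 on plate A and 11.7 on plate B), with Aldoa at 440.5 and 792 CPM and Ldha at 228 and 453. Slc2a3, Hk2 and Ldhb were at least 4-fold higher in the microglia class and Hk1 in endothelial cells, with Hk2, a hexokinase, at 64.3 against 0.0468 CPM. Hk1, Slc2a3 and Ldhb were named after their values were seen. All 17 measured oxidative phosphorylation genes lay within 4-fold (median -0.15, -0.32 within plate A and -0.34 within plate B), with Atp5b at 619 and 954 CPM. Of 17 measured cell cycle genes, 10 were at least 4-fold higher in the microglia class (median 2.37, 1.49 within plate A and 3.75 within plate B, but 0.01 for cluster 3 alone). The list stood at percentile 97.1 pooled and 39.2 on plate A, below the median of all genes there. For several members 1 cell held most reads of the class: 99.5% for Rrm2, 98.3% for Ccnb2, 93.1% for Ube2c and 87.8% for Birc5, genes named after their values were seen. Cenpf, a kinetochore protein, was at 47.9 against 0.187 CPM, and Pcna, a replication clamp, at 99.6 against 36, while Tubb5, a tubulin, was at 399 and 1166.

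**Figure D3:**
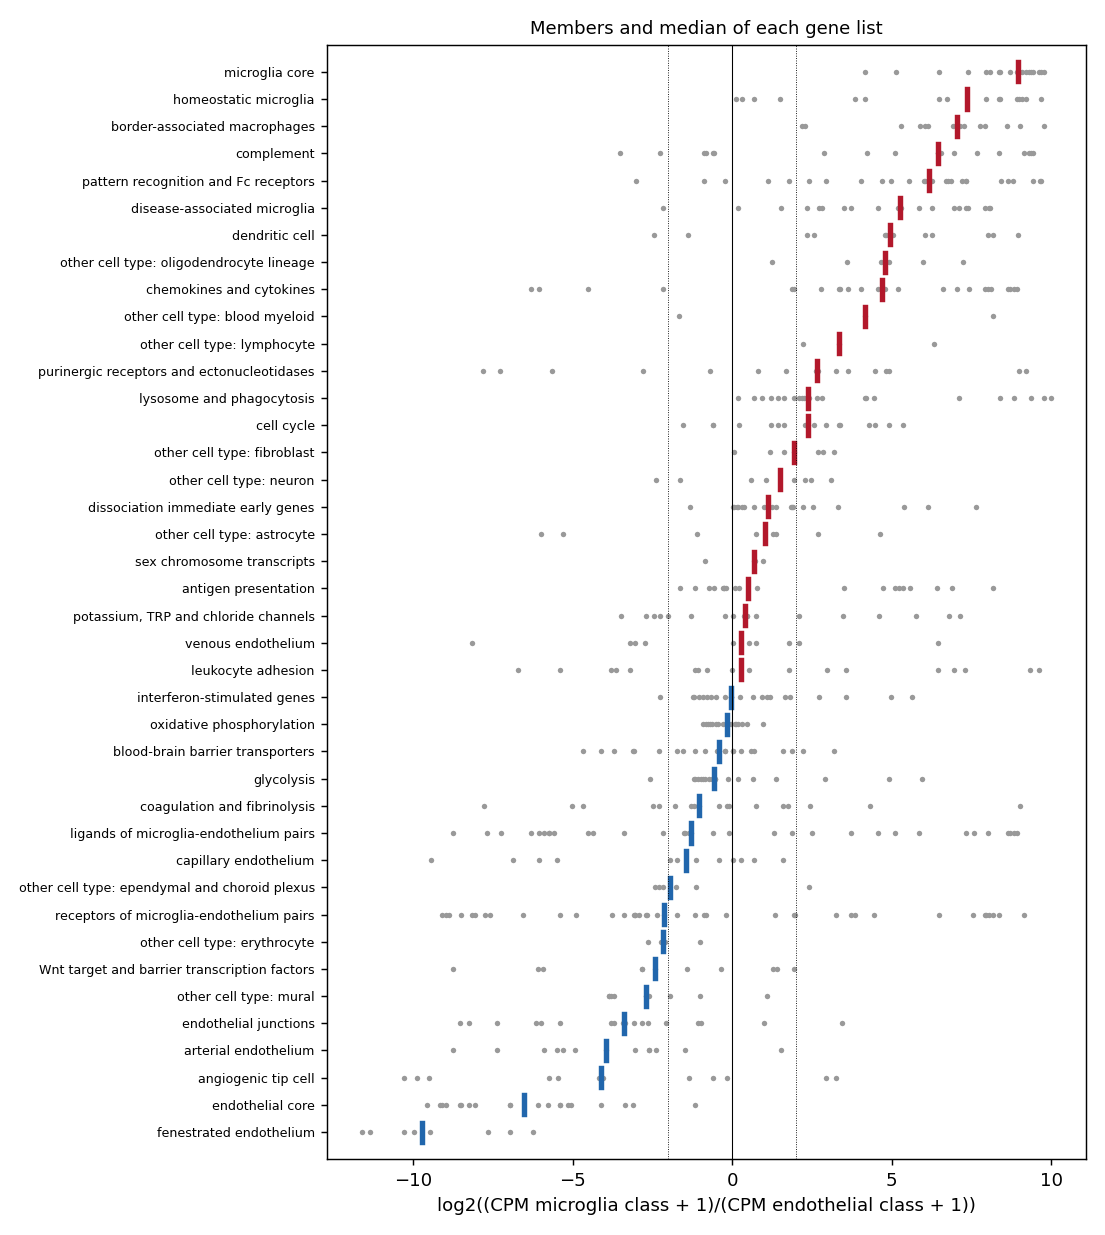
Log2 ratio of pooled CPM plus 1, microglia class over endothelial class, for each measured member (grey points) and the median (coloured bar) of each of 40 gene lists. Dotted lines mark 4-fold. Medians ran from -9.73 for fenestrated endothelium to 8.97 for the microglia core.

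The genes with the largest ratios were taken among those at 50 CPM or more and read in at least 50% of the higher class. On the microglia side, Tnf, the inflammatory cytokine, was at 479.9 CPM in the microglia class and read in 64.6% (58.7 to 70.2) of its cells, against 1 read in endothelial cells, a ratio of 10251-fold (1839.7 to 404919). Themis2, Pik3ap1, Nfkbid, Lpxn, Lrrc25, Ccl12, Clec12a, Mpeg1, Cd52, Ms4a6b and Cd300c2 followed, at 239 to 557 CPM in the microglia class and with 1 or 2 reads in endothelial cells (at most 0.0936 CPM), so their order rests on those few reads. On the endothelial side, Stc1, stanniocalcin, stood at 415 CPM against 1 read, Col13a1, a transmembrane collagen, at 959.7 CPM against 0 reads (at least 15198-fold higher, from a floor of 3 reads over the class), and Piezo2, a mechanosensitive channel, at 311 CPM. Sema3f, Esm1, Btnl9, Ces2e, Trib2, Kcnq1, Igfbp3, Plvap and Hspg2 completed the list. The most abundant genes of the microglia class were Rn18s-rs5, Apoe, mt-Rnr2, Actb and Ctsb, and those of endothelial cells Rn18s-rs5, Plvap, mt-Rnr2, Igfbp3 and Eng. Counts per exon base appear limited, as described below, so the order of the most abundant genes is uncertain. Actb, beta-actin, was at 5121 and 4570.4 CPM.

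Core markers of the other class were read at a low level. Whether those reads were carried over or were the cells' own was not tested. The summed endothelial core level in the microglia class was 1.47% of that in endothelial cells (median cell 0.702%), and 1.06% within plate A and 1.47% within plate B. Eng, Slc2a1 and Egfl7 held 24.9%, 17.5% and 15.3% of those reads. Eng and Egfl7 were uneven over the clusters of the microglia class. Eng stood at 312 CPM in cluster 3 and 9.15 in cluster 4, and Egfl7 at 172 in cluster 1 and 4.03 in cluster 3. The summed microglia core level in endothelial cells was 0.482% of that in the microglia class (median cell 0.119%), and 0.711% and 0.363% within the plates. In 17 microglia-class cells and 1 endothelial cell the level reached 5%. A share of cells with a read is therefore no sign of expression at such levels: C1qb was read in 48.6% of endothelial cells at 5.48 CPM, and Flt1 in 67.9% of microglia-class cells at 7.87 CPM.

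Markers of further cell types were mostly low. Oligodendrocyte genes were higher in the microglia class, 5 of 6 measured at least 4-fold (median 4.81, 4.37 within plate A and 4.31 within plate B, at percentile 72.7 on plate B), with Mbp, the myelin basic protein, at 229 CPM against 0.515. Of 10 measured mural genes, 7 were at least 4-fold higher in endothelial cells (median -2.70, but 1.60 within plate A and 0.06 within plate B, where 5 and 3 members were measured, at percentile 0.03 pooled, 46.9 on plate A and 1.97 on plate B), with Acta2, smooth muscle actin, at 132 against 8.12 CPM. The astrocyte list had a median of 1.02 (1.43 and 0.32 within the plates) at percentile 77.7 pooled, with Clu and Gja1 at 565 and 352 CPM in endothelial cells and Slc1a3 at 60.6 in the microglia class. Fibroblast, neuron and ependymal or choroid plexus lists had medians of 1.94 (1.60 and 2.35 within the plates), 1.50 (2.01 and 2.46 within the plates) and -1.96 (-0.81 and 3.77 within the plates). Pooled, these lists stood at percentiles 50.3, 58.1 and 0.35 of the random lists. Their most abundant members, Dcn, Stmn2 and Ttr, reached at most 14.3, 11.7 and 40.1 CPM. Erythrocyte genes had a median of -2.17 (-1.25 and 0.34 within the plates), with Hbb-bs at 22.4 CPM in endothelial cells. Only 3 blood myeloid and 3 lymphocyte genes were measured, with medians of 4.17 (1.79 and 4.84 within the plates) and 3.36 (4.06 and 2.73 within the plates). Ccr2, a receptor of monocytes, was at 289.9 CPM in the microglia class with 0 reads in endothelial cells, and Cd79b, a B cell receptor chain, at 84 against 0.0468.

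Transcripts of the sex chromosomes showed no more than 1 read of Xist, the RNA of the inactive X, in any of the 391 cells, with 24 reads in total. Reads of the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were present in 246 cells, and the list's median was 0.70 (1.17 and 3.96 within the plates). Ddx3y stood at 68.5 and 124 CPM, Eif2s3y at 70.9 and 44.1, Uty at 23.6 and 13.9, Kdm5d at 17.7 and 8.57, and Xist at 0.463 and 0.0936. Tsix had 0 reads in both classes. Of the 22 microglia-class cells with an Xist read, 21 came from plate A.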

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

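The values within single plates and for cluster 3 alone were chosen after seeing the data; the others were chosen beforehand. Under 10 alternatives chosen beforehand, 381 of 400 list medians stayed within the interval of their median and 19 moved, and no median outside the central 95% of its random lists changed sign. That interval is a 95% interval from the ranked log2 ratios of a list's members. It can be wide, as for adhesion (-3.20 to 6.46), where 3.79 on plate A still counted as within it. Staying within the interval is therefore a weak check. Counts of members at 4-fold, for the 10 lists tried, stayed within 1.5 times in all 100 such values. Of 1110 log2 ratios of named genes, 1057 moved by less than 1.5 times and 53 by more. Within single plates and for cluster 3, 268 of 555 moved by less, 267 by more and 20, all at least 4-fold apart pooled, changed sign; of 120 list medians 103 stayed within their interval. Over all alternatives 25 of 40 list medians kept their sign. Raising the minimum to 10 reads lowered 320 shares of cells beyond their intervals, and thinning moved 188, of which 187 were lower, so shares depend on depth.

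Within plates, with only 7 and 10 endothelial cells, some values changed sign; those of lists outside the central 95% of their random lists and of genes at least 4-fold apart pooled are named, which leaves out others, such as Slc2a1 and glycolysis on plate A and erythrocyte genes on plate B. The ligand list's median was 0.0514 on plate A and 0.11 on plate B, the mural list's 1.60 and 0.0622, and the ependymal and choroid plexus list's 3.77 on plate B, with 2 members measured. The ligand and mural values lie below the median of all genes on their plate, 1.73 and 1.87, but of these only the mural list on plate B stayed outside the central 95% of random lists. On plate A log2 ratios changed sign for Csf1 (4.54), Piezo1 (4.64), Acta2 (1.65), Rgs5 (0.42), Des (0.73), Myh11 (0.31), Stmn2 (2.16), Hba-a2 (0.31), Rarres2 (0.62) and Zbtb46 (2.67). On plate B they did so for Piezo1 (0.0134), Acta2 (0.28), Des (0.22), Rarres2 (0.30) and Hbb-bs (2.37). With cluster 3 alone, log2 ratios changed sign for Cxcr4 (-0.92), Dab2 (-3.02), Slc6a13 (-0.0660), Meg3 (-0.20) and Plac8 (-0.0542), and 4 border-associated macrophage genes stayed at 4-fold. Fewer endothelial or microglia-class cells enter these values by construction; apart from that the cause was not tested.

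The endothelial core level in the microglia class was 1.41% with mean per-cell CPM, 1.39% with TMM, 0.986% without cells at 5%, 1.30% without each gene's highest cell, 1.06% on plate A and 2.50% for cluster 3. The microglia core level in endothelial cells was 0.418%, 0.509%, 0.427% and 0.355% under the same 4 alternatives, 0.711% and 0.363% on plates A and B, and 0.270% against cluster 3. Median genes per cell were 2177 and 2086 when thinned, by construction, and 2775 for the microglia class on plate B. Median gene reads were 122714 and 199821 for the microglia class and 135028 and 185736 for endothelial cells on plates A and B. At resolution 1.0 the endothelial class gave 4 clusters instead of 1; the cause was not tested. The microglia class gave 5 clusters instead of 4 at resolution 1.0 and with 1000 variable genes. The microglia-like cluster held 51 or 52 cells under each of the 3 other cluster settings.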

Other observations

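Pairs of signalling genes differed in how far they were split between the classes. These genes were picked after their values were seen. Endothelial cells carried Cx3cl1 at 1133 CPM (microglia class 13.5), and the microglia class its receptor Cx3cr1 at 2067 (endothelial cells 5.2). Tnf stood at 479.9 CPM in the microglia class, and its receptor Tnfrsf1a at 738 in endothelial cells and 403 in the microglia class. Gas6 was at 1624 CPM in endothelial cells and 661 in the microglia class, and its receptors Axl and Mertk at 422 and 344 in the microglia class and 0.749 and 88.9 in endothelial cells. Class values hide differences between clusters 1 to 4: Axl stood at 187, 1088, 104 and 394 CPM, Mertk at 319, 183, 832 and 1.96 and Gas6 at 1276, 429.7, 289 and 48.7. Csf1, a ligand of Csf1r, was at 116 CPM in endothelial cells, though 0 in the 7 of plate A, while Il34, the other, was at 0.14 there and 0.337 in the microglia class. Endothelial cells carried both Cxcl12 and its scavenging receptor Ackr3, at 828 and 619 CPM.

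Of the tests below, those of the fenestrated endothelium and of the immediate early genes were set before their result was seen; the others were chosen after. The fenestrated type of the endothelial cells was a hypothesis drawn from their class code in the deposited cell table, CP-EC, which is not spelled out there. The test of the explanation that the endothelial cells are fenestrated (permeable) rather than barrier endothelium was the percent of endothelial cells with a Plvap read, with its CPM against Slc2a1 and Mfsd2a. Plvap was read in 100% of the 111 cells and stood above both, which is consistent with fenestrated endothelium. Which vessels the cells came from is open, since the labels give the tissue only as brain and the sources used here do not explain the code.

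The microglia class held cells with different macrophage programs; a difference between plates as the whole source is argued against, as the cluster most tied to 1 plate had 74.2% of its cells there. Wells holding 2 cells stay open: cells with both markers made up 5.56% of those with Sall1 alone for Sall1 and Mrc1, genes that tell the clusters apart, but 85 cells had P2ry12 and Mrc1 together against 56 with P2ry12 alone. For free RNA or spilled reads, the summed border-associated macrophage level in endothelial wells of the shared plates was 2.93% of that in cluster 1, which did not decide. Endothelial cells carried Stab1 and Dab2 at 12.4% and 8.47% of the cluster 1 level on the plates without microglia-class cells, and the other 12 members summed to 0.0891% on the shared plates, which argues against RNA spread over the whole plate for those 12. Spill between neighbouring microglia-class wells stays open, since endothelial wells lay in rows A to H and microglia-class wells in rows I to P, and no biological explanation was tested, as the labels name no macrophage subtypes.

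Cluster 4 may hold dendritic cells: a list of 14 such genes, written after the cluster's leading genes were known, had a median log2 ratio of 2.54 over the other cells of the class (4.94 for the whole class over endothelial cells), with 6 genes read in at least 50% of its cells. Of the list, 7 genes were at least 4-fold higher in it than in the rest of the class. Cd209a stood at 2812 CPM in cluster 4, Flt3 at 174 and Irf4 at 260. Irf8 at 98.8 was however below the 1157 of cluster 2, and Xcr1 and Ccr7 had 0 CPM in all 4 clusters. Ccr2 and Itgax also stand in other lists. The cell cycle and blood myeloid lists had medians of 3.17 and 3.32 in cluster 4, with only 2 of 20 and 1 of 11 genes read in at least 50% of its cells. Of the blood myeloid list, Ccr2 stood at 796 CPM in cluster 4, Ly6c2 at 0.131, and Chil3, Camp and Cd177 at 0. Members thus went both ways, and blood myeloid cells stay open. Wells holding 2 cells are argued against for partners of cluster 3 and the endothelial class, where the median core gene stood at 5.32% and 0.214% of the partner's level, and for cluster 1, where it was 13.4%, which did not decide, but border-associated macrophage genes, tried next, stood at 0.571%. For cluster 2 these lists stood at 9.497% and 8.07%, near the bound of 10%. Stab1, Ms4a7 and Pf4 stood at 11.6, 8.1 and 7.32 CPM against 1208, 816 and 603. Other members went the other way, with Mrc1 at 633 against 1752, Dab2 at 221 against 802, Clec12a at 359 against 481 and Cd163 at 156 against 149. Wells with a partner of cluster 2 therefore stay open.

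Immediate early genes were higher in the microglia class. Plates as the whole source are argued against, as the lower of the medians within plates A and B was 0.89. That is below the median of all genes on the plate, 1.73, so the reading rests on the comparison with lists matched on expression, where it stood at percentile 99.9. The mixture of macrophage types is argued against too, as cluster 3 alone gave 1.23. Whether dissociation or the state of the cells in the brain sets the difference stays open and was not tested, since no cells were taken without dissociation.

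The most abundant short transcripts had fewer reads than the depth would allow. Among 8592 genes with 1000 or more reads and an exon length in the older annotation (97.6% of such genes), the highest count was 1.57 reads per exon base, and 0 genes exceeded 2. Rn18s-rs5 had 1677 reads in the median cell and at most 1929, although total reads differed 15.1-fold between cells. A candidate explanation is that reads at the same position were collapsed before counting. It predicts that abundant genes gain few reads with depth. Few genes could be tried at 0.3 or more reads per base, 13 in the microglia class and 6 in the endothelial class. Genes at 0.03 to 0.1 numbered 52 and 74. The slope of log2 reads on log2 total reads was lower by at least 0.55 for the first set than for the second, in both classes. If reads were collapsed, CPM values and ratios of the most abundant genes, such as Plvap, C1qb and Cd74, would be understated. No other explanation of the pattern was tested.

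All cells may have come from male animals. Reads of Y-linked genes were present in 246 of 391 cells, on each plate in both classes, and no cell had more than 1 Xist read. That the counting left out most Xist reads was not tested.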
